A study of Mus musculus with 16 samples.

How the data were processed

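Gene expression was measured in mouse liver on 16 Agilent whole-genome arrays read in 2 colours, each array carrying RNA of one genotype in Cy3 and of another in Cy5. The genotypes were wild type, Nrf2 knockout (Nrf2 KO; Nrf2 is the product of the gene Nfe2l2), a conditional knockout of the autophagy gene Atg7 (Atg7 cKO; floxed alleles removed by Cre under the Mx1 promoter, which pIpC induces) and the double knockout of both genes. Per the labels, mice received pIpC at 8 weeks of age, livers were taken 4 weeks later, and total RNA was purified with TRIzol and then RNeasy. The 16 arrays formed 8 dye-swapped experiments. A dye swap was counted as 1 replicate, which gave 2 experiments per comparison: experiments 1 and 4 set Nrf2 KO against wild type, 2 and 5 set Atg7 cKO against wild type, 3 and 6 set the double knockout against wild type, and 7 and 8 set the double knockout directly against Atg7 cKO. From the barcodes in the file headers, experiments 1 and 2 shared a slide, as did 3 and 4, and 5 and 6.

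The scanner files of experiments 1 to 6 (12 arrays) held the mean signal and the median local background of each spot as intensity per the file headers. Per the file headers they were made with Agilent Feature Extraction 9.5.1.1 (9.5.1 per the submitters' processing notes) and the protocol GE2-v5_95_Feb07, with probe coordinates on build mm9. The same files held processed signals (background-subtracted, spatially detrended and dye-normalised per the file headers), the log10 ratio of processed Cy5 to processed Cy3 signal, and flags for signal well above background, saturation and outlying pixels or spots. The deposited value table held log10 ratios, in a column for each of the 16 arrays. Each of the 12 columns with a scanner file differed from the log10 ratio of that file by less than 0.005 at every probe compared, so the table holds Cy5 over Cy3, and each of the 16 columns had a median of 0. For experiments 7 and 8 the value table was used and no scanner file was read.

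Medians of the mean signal lay between 41.82 and 55.63 over the arrays and channels, against median backgrounds of 34.5 to 36.5. Between 43.42% and 57.19% of the 43379 spots were well above background, at most 1 spot per channel was saturated, and 102 to 132 spots per array carried an outlier flag. The number of arrays limits the precision of every value.

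Signals were corrected with normexp (offset 50, mean signal and median background) and normalised by loess within each array in limma 3.58.1 under R 4.3.3 with data.table (version 1.17.8). Log2 ratios were turned to knockout over partner and the arrays of a dye swap averaged. Control spots and spots with an outlier flag were left out. A probe was kept if well above background in at least 4 of the 24 channels, and a gene with several kept probes was represented by the brightest. Probe names were updated from a table of RefSeq accessions and symbols that belongs to a later genome build, from which no coordinate was taken: 24844 of 41174 probes were named by accession, 6045 by symbol, and 10285 kept the name in the file. Of 28632 gene names, 16673 had a kept probe and 16671 were tested.

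One limma fit with 3 group means over experiments 1 to 6 gave the comparisons with wild type, the double knockout against Atg7 cKO through wild type, and the interaction (double knockout minus Atg7 cKO minus Nrf2 KO, a departure from additivity on the log2 scale). A second fit with 4 group means over all 8 experiments of the value table, converted to log2, gave the direct comparison. Residual degrees of freedom were 3 and 4, and the empirical Bayes priors added 2.21 and 2.14. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. They are set against the spread between experiments of the same group, taken as 1 value per gene pooled over all groups of a fit. A p-value of Nrf2 KO thus also carries the spread of Atg7 cKO and the double knockout. In each comparison with wild type the experiments were 1 of experiments 1 to 3 and 1 of experiments 4 to 6. Those sets differ in sex-linked transcripts, as given below, so the spread, like each SD, includes any difference in effect between the sets. The series' design text speaks of RNA from each mouse liver, but the labels give no animal numbers, so part of that spread may be technical rather than between animals. The offset shrinks ratios of dim genes: in simulated spots with a true log2 ratio of 2, the median estimate was 0.336 at signals under 50, 1.638 between 50 and 500 and 1.941 above 500. In tests on simulated data with 200 altered genes, 2-fold changes were recovered for 95.5% of genes in Nrf2 KO, 98.5% in Atg7 cKO, 91.0% in the double knockout and 47.8% in the direct comparison, with 7, 17, 11 and 8 false calls in 16671 genes. These simulations drew normal noise at each gene's fitted spread and added the full change after processing, so shrinkage by the offset did not enter. They check the fit and give no power for the measured data. There 40 genes had a mean of at least 2-fold in Nrf2 KO, and 2 were called.

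A total of 32 lists were tested with camera at a preset correlation of 0.01 and again with the correlation estimated from the data, adjusted over the lists within a comparison; fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, was run beside them. The lists were NRF2 targets of glutathione metabolism; NRF2 targets of quinone, aldehyde and thiol reduction; pentose phosphate pathway and NADPH supply; autophagy machinery; lysosome; proteasome; cytochrome P450; bile acids; fatty acid oxidation and PPAR alpha targets; fatty acid synthesis; cholesterol synthesis; gluconeogenesis and glycolysis; urea cycle and amino acid catabolism; hepatocyte secreted proteins and transcription factors; acute phase proteins; interferon response; unfolded protein and integrated stress response; cell cycle; p53 targets; circadian clock; pericentral and periportal hepatocyte; male-biased and female-biased liver genes; Y-linked genes with Xist; and markers of macrophages, stellate cells, cholangiocytes and progenitors, endothelium, lymphocytes, neutrophils and erythroid cells. Named genes were Atg7, Nfe2l2, Keap1 and Sqstm1 in every comparison; per comparison the 8 largest rises and the 8 largest falls among genes with adjusted p under 0.05 that moved the same way on every array and had a proper symbol rather than a clone or predicted-gene name; and up to 4 members of each list with the smallest adjusted p. Other members are given where a sentence on a list needs them. Some genes that the rule selects are not reported here. The groups, comparisons, tests, lists, naming rule and alternatives were fixed before the data were examined, except where stated.

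Alternatives were Feature Extraction's processed signals, the value table, no background correction, an offset of 10, centring on the median, scaling between arrays, no filter, a filter of 12 channels, outlier spots kept, the mean over probes, a dye effect with experiment as a random block (consensus correlation 0.676), each dye alone, slide as a block, experiments 1 to 3 against 4 to 6 as a block, each comparison's own experiments, a 2-fold minimum, adjusted p under 0.01, and leaving out each experiment. Chosen after the data were seen were the filter of 12 channels for the direct comparison and 2-fold counts in experiments 1 to 3 and 4 to 6 alone. No comparison of samples drawn as other splits was made, since each group has 2 experiments. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.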

Results

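Liver RNA of mice with a knockout of Nrf2, a conditional knockout of Atg7, or both was set against wild-type RNA on 2-colour arrays, 2 dye-swapped experiments per comparison, and the double knockout was also hybridised directly against Atg7 cKO in 2 further experiments. Atg7 encodes an enzyme needed to form autophagosomes, and Nrf2 is a transcription factor that activates antioxidant and detoxification genes. The design addresses which changes of the autophagy-deficient liver depend on Nrf2. Over 16665 to 16671 genes the log2 ratios of the 2 dye orientations correlated across genes with Pearson's r of 0.591 and 0.469 in the Nrf2 KO experiments 1 and 4 and of 0.934 and 0.936 in the Atg7 cKO experiments 2 and 5. It was 0.957 and 0.923 in the double knockout experiments 3 and 6 and 0.818 and 0.790 in the direct experiments 7 and 8. Between the 2 experiments of a comparison r was 0.246 (over 16652 genes) for Nrf2 KO, 0.853 for Atg7 cKO, 0.865 for the double knockout and 0.668 for the direct comparison. Genes are not independent replicates, so these correlations describe likeness and carry no test.

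The experiments fell into 2 sets that cut across the genotypes. In experiments 1 to 3 the Y-linked transcripts Ddx3y and Eif2s3y were well above background and Xist was not, and in experiments 4 to 6 the reverse held, in wild-type and knockout channels alike. The log2 signal of Xist in the wild-type channel was 5.76 to 5.80 in experiments 1 to 3 and 11.15 to 11.21 in experiments 4 to 6. The labels give no sex, but these transcripts were as in males in experiments 1 to 3 and as in females in experiments 4 to 6. Each comparison with wild type had 1 experiment in each set, and both channels of an array came from the same set, so the sets did not separate the genotypes. Wild-type channels deviated from their mean over experiments alike within a set (r across genes of 0.53 to 0.88). Slides held experiments 1 and 2, 3 and 4, and 5 and 6. Values from a fit with slide as a block are given beside the main ones for gene counts and for some of the lists. Set as a block means the grouping of experiments 1 to 3 against 4 to 6.

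The probes for the targeted genes followed the genotypes. For Nfe2l2 the brightest probe (A_51_P411271, mm9 chromosome 2, 75513771 to 75513830, on transcript NM_010902) gave log2 ratios of -3.88 ± 0.13 in Nrf2 KO (SD, n = 2; limma adjusted p = 0.0263) and -3.71 ± 0.56 in the double knockout (adjusted p = 6.7e-04). On the processed signals the same probe gave -6.785 in Nrf2 KO and -5.47 in the double knockout. In Atg7 cKO Nfe2l2 mRNA rose by 1.20 ± 0.10 (adjusted p = 0.00692). A neighbouring Nfe2l2 probe (A_52_P396436, 75513917 to 75513976) gave -3.04 in Nrf2 KO, 1.03 in Atg7 cKO and -3.04 in the double knockout. Another Nfe2l2 probe on a different transcript (A_52_P523835) lay at -0.06, -0.02 and 0.06. For Atg7 the probe A_52_P34494 (mm9 chromosome 6, 114726985 to 114727044, transcript NM_028835) gave -0.80 ± 0.02 in Atg7 cKO and -0.73 in the double knockout (adjusted p = 8.28e-04 in both) and -0.05 in Nrf2 KO. This probe is dim, and on the processed signals, which carry no offset, its log2 ratio was -3.42 in Atg7 cKO and -3.16 in the double knockout. A second Atg7 probe on another transcript (A_52_P550935) lay at -0.07, -0.08 and -0.03 in Nrf2 KO, Atg7 cKO and the double knockout. The labels do not state which exons were removed, so a probe that did not move may lie outside the deleted part and then checks nothing.

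Loss of Nrf2 alone changed few genes past the threshold. Besides Nfe2l2, 1 further gene passed, which carries a clone name (RP23-10A18.3, probe A_52_P402127) and was chosen for naming after its values were seen. Its log2 ratio was -1.5 (limma adjusted p = 0.0263). That made 2 genes lower and 0 higher out of 16671 by limma, with 616 at an unadjusted p under 0.05. The single experiments gave 72 genes past 2-fold in experiment 1 (20 up, 52 down) and 60 in experiment 4 (15 up, 45 down), without a test. Sqstm1, the autophagy receptor p62, and Keap1, the protein that holds Nrf2 inactive, lay at 0.00 ± 0.07 and -0.00 ± 0.04 (SD, n = 2). With slide as a block 4 genes passed, with set as a block 11, and with a dye effect and experiment as random block 91. None did when experiment 1, 2, 4 or 5 was left out (0 by limma, with at least 362 genes at an unadjusted p under 0.05).

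Known targets of Nrf2 nevertheless lay below wild type as groups. Of 24 measured targets in quinone, aldehyde and thiol reduction none passed over all genes, while 12 were lower and 0 higher when adjusted over the list alone. Their median log2 ratio was -0.38 (-0.42 with slide as a block, -0.38 and -0.50 in experiments 1 and 4; camera adjusted p = 6.21e-23). Examples that missed the threshold over all genes were Ugt2b35 at -1.54 ± 0.26 (adjusted p = 0.101), which glucuronidates foreign compounds, and Aox1 at -1.65 ± 0.44 (adjusted p = 0.213), an aldehyde oxidase. Of 21 measured targets in glutathione metabolism 5 were lower and 1 higher when adjusted over the list alone, with a median of -0.43 (-0.53 with slide as a block, -0.20 and -0.42 in experiments 1 and 4; camera adjusted p = 1.4e-10). Among these the glutathione transferase Gstm1 lay at -1.74 ± 0.01 (adjusted p = 0.329) and Mgst3 at 0.90 ± 0.25 (adjusted p = 0.448). The p-value of Gstm1 rests on a standard error of 0.198 from the spread pooled over the groups. With an estimated correlation neither list passed (adjusted p = 0.227 and 0.259).

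Camera called 8 other lists in Nrf2 KO. With the preset correlation it called fatty acid oxidation higher (median 0.19, adjusted p = 1.49e-07), proteasome subunits higher (0.05) and p53 targets higher (0.05). It called cytochrome P450 (-0.09), cholesterol synthesis (-0.18), the unfolded protein response (-0.12), pericentral genes (-0.14) and male-biased genes (-0.40) lower. None of these 8 calls held with an estimated correlation (adjusted p = 0.786 in each), and the median of male-biased genes became 0.11 with slide as a block. Without experiment 1 the median was 0.16 for cholesterol synthesis and -0.04 for the proteasome. Hepatocyte secreted proteins had a median of 0.08, within which the major urinary protein gene Mup1, whose product binds pheromones, lay at -1.78 ± 0.06 (adjusted p = 0.101). Acute phase proteins (-0.07), the interferon response (0.02), the cell cycle (0.06), the lysosome (-0.01), autophagy machinery (-0.03) and macrophage markers (0.03) were not called. The acute phase median was 0.07 in experiment 1 and 0.06 in experiment 4, and camera's direction was positive, against the negative median of the fitted ratios.

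Loss of Atg7 changed the liver transcriptome widely. Among the largest rises were Cbr3, a carbonyl reductase (log2 ratio 4.99 ± 0.26, SD, n = 2; limma adjusted p = 6.31e-05), and Srxn1, the sulfiredoxin that restores oxidised peroxiredoxins (4.18 ± 0.04, adjusted p = 3.13e-05), both targets of Nrf2. Spink1, a trypsin inhibitor induced in injured liver, rose by 5.03 ± 0.41, and Maoa, a monoamine oxidase, by 4.04 ± 0.04. Mup1 fell by 6.003 on the log2 scale (SD 0.04, adjusted p = 6.31e-05) and Car3, a carbonic anhydrase abundant in hepatocytes, by 3.60 (SD 0.19, adjusted p = 0.00562). The autophagy receptor gene Sqstm1, itself a target of Nrf2, rose by 1.40 ± 0.12 (adjusted p = 7.58e-04), and Keap1 was not called (0.20 ± 0.22, adjusted p = 0.137).

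In all, 3872 genes rose and 2701 fell in Atg7 cKO out of 16671 (6012 in all with slide as a block), and 1041 of the 6573 changed at least 2-fold (652 up, 389 down). Without experiment 5 the count was 3205. The largest rises by the naming rule also included Ly6d (4.08 ± 0.05), Elovl7 (4.05 ± 0.24), Abcc4 (3.97 ± 0.19) and Cyp2a4 (4.05 ± 1.66). Among the largest falls were Mup6 (-6.49 ± 1.29), Sult2a8 (-4.69 ± 0.15), Mup3 (-4.59 ± 0.07), Mup5 (-3.77 ± 0.53), Cyp4a10 (-3.50 ± 0.79) and Cyp2c54 (-3.29 ± 1.10). Near-identical paralogs among the Mup and Cyp2a genes leave uncertain which member each of their probes measured. Part of the Cyp2a4 rise lies in low wild-type signals on the Atg7 cKO arrays, as given below. The single experiments gave 940 genes past 2-fold in experiment 2 and 1387 in experiment 5.

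Targets of Nrf2 rose in Atg7 cKO. In quinone, aldehyde and thiol reduction 22 of 24 measured genes rose and 0 fell (23 and 0 adjusted over the list alone), with a median of 1.28 (1.28 with slide as a block, 1.41 and 1.28 in experiments 2 and 5; camera adjusted p = 1.11e-10). Among them Nqo1, which reduces quinones, rose by 2.23 and Txnrd1, which reduces thioredoxin, by 1.96. In glutathione metabolism 17 of 21 rose and 1 fell (17 and 1 over the list alone), with a median of 1.66 (1.72 with slide as a block, 1.80 and 1.71 in experiments 2 and 5; camera adjusted p = 1.36e-06). Gclc, the catalytic subunit for glutathione synthesis, rose by 2.55, Gpx2 by 3.40 and Gsta1 by 3.76, while Gsta3 fell by 1.03. Neither list passed with an estimated correlation (adjusted p = 0.275 for both). In the pentose phosphate pathway, which supplies NADPH, 5 of 9 rose and 1 fell, including Pgd at 1.97 and G6pdx at 1.36. The list was not called (median 0.65, camera adjusted p = 0.175).

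Lists of hepatocyte function were lower in Atg7 cKO. Of 25 genes of the urea cycle and amino acid catabolism 21 fell and 0 rose (22 and 0 adjusted over the list alone), with a median of -1.51 (-1.65 with slide as a block, -1.34 and -1.60 in experiments 2 and 5). Cps1, the entry enzyme of the urea cycle, fell by 2.12 and Hpd by 2.19. Of 24 hepatocyte secreted proteins and transcription factors 19 fell and 1 rose (20 and 1 over the list alone), median -1.01 (-0.99 with slide as a block, -1.0 and -0.94 in experiments 2 and 5). Albumin (Alb) fell by 1.41 and transthyretin (Ttr) by 1.16, and haemopexin (Hpx) rose by 0.96. Cytochrome P450 genes were split into 16 lower and 4 higher of 31 (median -1.09; -1.03 with slide as a block). Cyp2e1 fell by 2.95, and the genes that rose were Cyp2a4, Cyp2a5, Cyp2c55 and Cyp1a2. Bile acid genes (12 lower, 2 higher of 21, median -0.88) included Slc10a1, the importer of bile acids, at -2.19, and Cyp7a1 at -2.07. Fatty acid synthesis had 9 lower and 0 higher of 20 (median -0.99), and cholesterol synthesis 6 lower and 0 higher of 24 (median -0.31). Fatty acid oxidation had 15 lower and 4 higher of 32 (median -0.33), where Fgf21, a fasting hormone, rose by 1.35. Camera called each of these lists lower (adjusted p = 3.77e-09 for the urea cycle, 8.88e-09 for secreted proteins, 5.66e-04 for cytochrome P450, 0.00107 for bile acids, 5.66e-04 for fatty acid synthesis, 0.00521 for cholesterol and 0.0109 for fatty acid oxidation). With an estimated correlation none did (adjusted p = 0.399, 0.207, 0.552, 0.294, 0.426, 0.564 and 0.552 in the same order).

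Most genes of the interferon response, macrophages and the cell cycle rose in Atg7 cKO. Of 28 interferon response genes 23 rose and 0 fell (23 and 0 adjusted over the list alone; median 1.06, also 1.06 with slide as a block, 1.13 and 1.0 in experiments 2 and 5). The antiviral gene Rsad2 rose by 3.68 and the chemokine gene Cxcl10 by 3.47. Of 17 macrophage markers 15 rose and 0 fell (16 and 1 over the list alone; median 1.33; 1.37 with slide as a block, 1.11 and 1.58 in experiments 2 and 5). The scavenger receptor Marco rose by 3.34 and Trem2 by 2.43. Cell cycle genes rose in 22 of 24 cases and fell in 1 (median 1.36; 1.40 with slide as a block), among them Mki67 at 2.06. Targets of p53 rose in 14 of 17 cases with 0 lower (median 0.85; 0.88 with slide as a block), among them Cdkn1a at 1.06. Lysosomal genes had 16 higher and 1 lower of 26 (median 0.43), and stellate cell genes 10 higher and 0 lower of 15 (median 0.34, with Col1a1 at 2.21). Cholangiocyte and progenitor genes had 6 higher and 0 lower of 11 (median 0.58, with the fetal gene Afp at 3.72). Camera called these lists higher (adjusted p = 2.97e-08 for interferon, 1.14e-07 for macrophages, 2.97e-08 for the cell cycle, 2.81e-05 for p53, 3.54e-04 for the lysosome, 4.7e-04 for stellate cells and 0.00704 for cholangiocytes). With an estimated correlation none passed (adjusted p = 0.275, 0.399, 0.426, 0.275, 0.426, 0.275 and 0.275 in that order).

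The remaining lists of Atg7 cKO included some that were not called. Endothelial markers were not (2 higher, 0 lower of 15, median 0.01, camera adjusted p = 0.719). Neither were acute phase proteins, whose members went both ways (5 higher, 3 lower of 20, median -0.04, adjusted p = 0.943), with Lcn2 at 2.11 and Crp at -1.28. Proteasome subunits had 2 higher and 2 lower of 32 (median -0.02), and autophagy machinery 3 higher and 7 lower of 29 (median -0.06). Gluconeogenesis and glycolysis had 7 higher and 4 lower of 20 (median -0.04), where hexokinase 2 (Hk2) rose by 1.51 and Fbp1 fell by 1.62. The unfolded protein response had 11 lower and 2 higher of 22 (median -0.36, camera adjusted p = 0.00665), with Herpud1 at -1.06 and Atf3 at 1.18. The circadian clock had 3 lower of 13 (median -0.30), pericentral genes 6 lower and 1 higher of 11 (-0.62) and periportal genes 6 lower of 11 (-0.87). Camera called these 4 lists lower, and none passed with an estimated correlation (adjusted p = 0.486, 0.294, 0.552 and 0.547). Lymphocyte markers (6 higher of 15, median 0.13), neutrophil markers (2 higher of 8, median 0.20), erythroid genes (1 lower of 4, median -0.77) and Y-linked genes with Xist (0 of 5 by limma, median -0.05) were not called as lists. Male-biased liver genes had 4 lower of 9 (median -1.84, camera adjusted p = 0.0134, and 0.552 with an estimated correlation; -2.38 and -0.61 in experiments 2 and 5). Female-biased genes had 1 higher and 2 lower of 11 (median -1.34; -0.03 and -2.20 in experiments 2 and 5) and were not called.

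Most targets of Nrf2 did not rise in the double knockout liver, while most interferon, macrophage and acute phase genes did. Its largest rises included Marco (4.43 ± 0.22, SD, n = 2; limma adjusted p = 2.31e-04), Cxcl10 (4.40 ± 0.78), Rsad2 (4.26 ± 0.32), and the protease inhibitor Slpi (4.09 ± 0.24). They also included Tgtp1 (3.91 ± 0.08), the neutrophil chemokine Cxcl1 (3.80 ± 0.24) and serum amyloid A1 (Saa1, 3.69 ± 1.20, adjusted p = 0.00282). The largest falls included Mup1 (-5.68 ± 0.40), Mup6 (-5.37 ± 1.47), Mup5 (-4.99 ± 0.80) and the carboxylesterase Ces1f (-4.08 ± 0.39), with Sult2a8 (-3.82 ± 0.80), Dct (-3.63 ± 0.91) and Etnppl (-3.41 ± 0.90) next. Srxn1 lay at -0.33 (adjusted p = 0.00892), and Sqstm1 at 0.51 ± 0.17 against wild type (adjusted p = 0.00714). In all 3537 genes rose and 2648 fell of 16671 (5430 in all with slide as a block), 1064 of them at least 2-fold. Without experiment 3 the count was 2857 and without experiment 6 it was 3425. The single experiments gave 1304 genes past 2-fold in experiment 3 and 1104 in experiment 6. Keap1 lay at 0.06 ± 0.13 and was not called.

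**Figure D1:**
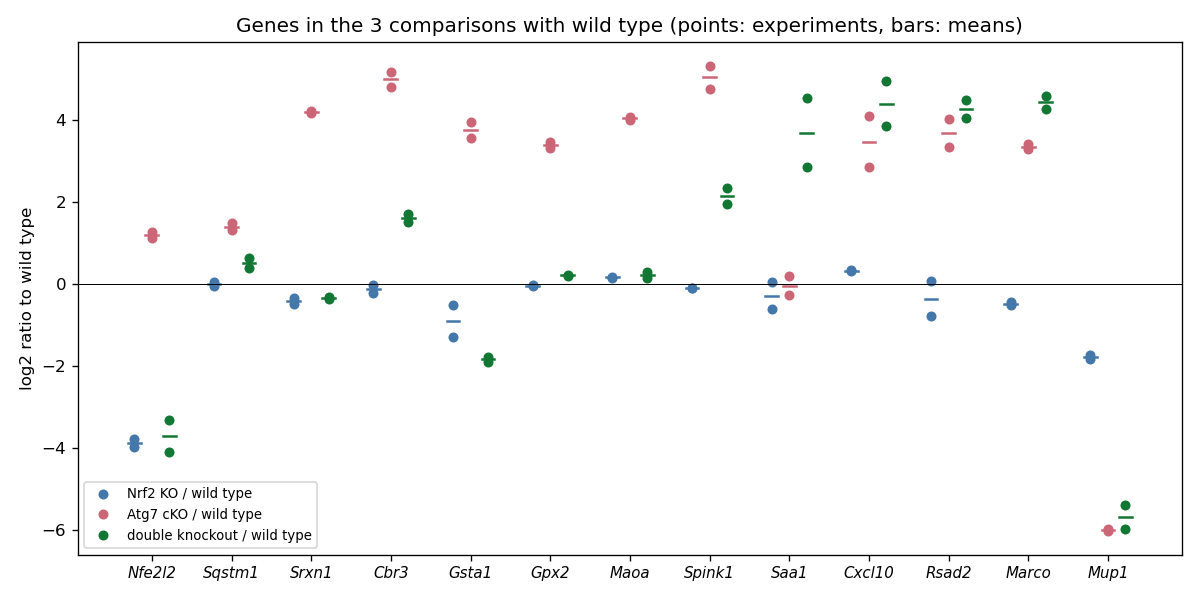
Log2 ratios to wild type of 13 genes in Nrf2 KO, Atg7 cKO and the double knockout; points are the 2 experiments of each comparison and bars their means. Srxn1 and Gpx2 stand at 4.18 and 3.40 in Atg7 cKO and near 0 in the double knockout, while Mup1 is at -6.003 and -5.68 and Marco at 3.34 and 4.43.

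Of 21 glutathione genes 11 were below wild type in the double knockout and 1 above (12 and 1 adjusted over the list alone; median -0.59; -0.52 with slide as a block, -0.46 and -0.71 in experiments 3 and 6; camera adjusted p = 0.00115), such as Gsta3 at -2.24 and Gsta1 at -1.84. Of 24 genes of quinone, aldehyde and thiol reduction 14 were lower and 4 higher (14 and 5 over the list alone; median -0.41; -0.42 with slide as a block, -0.37 and -0.52 in experiments 3 and 6; camera adjusted p = 0.00399). The 4 that rose without Nrf2 were Cbr3 at 1.61, the haem oxygenase gene Hmox1 at 1.53, Akr1b8 at 0.60 and Sqstm1. The rise of Cbr3 is uncertain, because its direct comparison and that through wild type disagreed, as given below. Neither list passed with an estimated correlation (adjusted p = 0.336 and 0.386). In the pentose phosphate pathway G6pdx rose by 1.21, 3 of 9 genes fell and the list was not called (median -0.01).

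Acute phase and interferon genes rose in the double knockout. Of 20 acute phase genes 16 rose and 0 fell (17 and 0 adjusted over the list alone; median 1.85; 1.79 with slide as a block, 2.26 and 1.51 in experiments 3 and 6; camera adjusted p = 1.8e-07), with haptoglobin (Hp) at 2.95 and Lcn2 at 3.03. All 28 interferon response genes rose (median 1.91; 2.02 with slide as a block, 1.91 and 1.79 in experiments 3 and 6; adjusted p = 2.21e-14), with Gbp2 at 2.77 and Isg15 at 2.67. All 17 macrophage markers rose (median 1.53; 1.49 with slide as a block, 1.65 and 1.44 in experiments 3 and 6; adjusted p = 1.97e-09), with Cd14 at 3.25. Cell cycle genes had 20 higher and 1 lower of 24 (median 0.87, adjusted p = 6.53e-07), and p53 targets 14 higher and 1 lower of 17 (0.73, adjusted p = 1.43e-05). The lysosome had 15 higher and 2 lower of 26 (0.46, adjusted p = 0.00213), with Ctss at 3.30, and stellate cells 10 higher of 15 (0.65, adjusted p = 3.88e-04). Lymphocytes had 8 higher of 15 (0.36, adjusted p = 0.00399) and neutrophils 5 higher of 8 (0.41, adjusted p = 0.00352), with S100a9 at 3.27. Retnlg, a neutrophil gene not well above background in wild type, was at least 1.42-fold higher. Such a fold is taken from the offset signals and is a lower bound. Cholangiocyte genes had 4 higher of 11 and were not called (median 0.28; adjusted p = 0.114, and 0.0455 with slide as a block). With an estimated correlation none of these lists passed (adjusted p = 0.386 for acute phase, 0.336 for interferon, 0.368 for macrophages, 0.431 for the cell cycle and for the lysosome, 0.336 for p53, stellate cells and neutrophils, and 0.466 for lymphocytes).

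Lists of hepatocyte metabolism were called lower in the double knockout as well. The urea cycle and amino acid list had 21 lower and 1 higher of 25 (median -1.33; -1.26 with slide as a block, -1.53 and -1.14 in experiments 3 and 6; camera adjusted p = 2.38e-08), and cytochrome P450 16 lower and 0 higher of 31 (-1.15; -0.87 with slide as a block; adjusted p = 1.09e-06). Bile acids had 12 lower and 1 higher of 21 (-0.82, adjusted p = 1.05e-04) and fatty acid oxidation 22 lower and 2 higher of 32 (-0.63, adjusted p = 6.53e-07). Hepatocyte secreted proteins had 14 lower and 6 higher of 24 (median -0.56; -0.54 with slide as a block; adjusted p = 0.0205). Alb fell by 1.41 and Cebpa by 1.21. The 6 that rose (Hpx at 3.10, Ambp, Fgb, Fgg, Fga and Trf) include fibrinogen and haemopexin genes that are themselves known to respond to inflammation. Fatty acid synthesis (3 lower of 20, -0.42), cholesterol synthesis (4 lower of 24, -0.29), the circadian clock (4 lower and 1 higher of 13, -0.35) and pericentral genes (5 lower of 11, -0.82) were called lower too, as were periportal genes (8 lower and 2 higher of 11, -1.25), male-biased genes (3 lower of 9, -1.43) and female-biased genes (1 lower of 11, -1.21). The male-biased median was -2.84 in experiment 3 and -0.16 in experiment 6, and the female-biased median -0.14 and -2.20, so each call rests mainly on 1 experiment. The same held for cholesterol synthesis (-0.68 and -0.05 in experiments 3 and 6) and the circadian clock (-0.44 and -0.08). The pericentral call was lost with slide as a block (median -0.61, adjusted p = 0.0608). None of these 12 lists passed with an estimated correlation, where adjusted p-values ran from 0.336 for bile acids to 0.643 for cholesterol. Gluconeogenesis and glycolysis (6 higher, 10 lower of 20, median -0.24), autophagy machinery (1 higher, 8 lower of 29, median 0.01) and the proteasome (7 higher, 3 lower of 32, 0.03) were not called. Neither were the unfolded protein response (2 and 2 of 22, 0.07), endothelial cells (1 higher, 4 lower of 15, -0.11), erythroid genes (1 lower of 4, -0.45) and Y-linked genes with Xist (0 of 5 by limma, 0.04).

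Set directly against Atg7 cKO, the double knockout had lower Nrf2 targets and higher acute phase genes. Cbr3 lay at -5.21 ± 0.25 (SD, n = 2; limma adjusted p = 2.72e-04), Srxn1 at -4.69 ± 0.04 (adjusted p = 2.55e-05), Gsta1 at -5.01 ± 0.04 (adjusted p = 4.03e-04) and Gclc at -3.22 ± 0.04. Serum amyloid genes, produced by hepatocytes under inflammatory cytokines, were higher, Saa1 by 3.73 ± 0.996 (adjusted p = 0.00928), Saa2 by 3.76 ± 0.79 and Saa3 by 3.62 ± 0.89. Through wild type, from separate arrays, the same genes gave -3.38 for Cbr3, -4.52 for Srxn1, -5.59 for Gsta1 and 3.72 for Saa1 (adjusted p = 0.0356 for Saa1). Those arrays may carry the same RNA extracts. For Cbr3 the direct value and that through wild type differed, and on processed signals the latter was -3.06. Its mean log2 signals were 8.72 in the double knockout and 14.46 in Atg7 cKO. Size and sign of the Cbr3 change between the double knockout and wild type are therefore uncertain.

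By limma, 1120 genes were higher and 1345 lower of 16671 in the direct comparison, and 1008 differed at least 2-fold (415 up, 593 down). Without experiment 7 the count was 307, without experiment 8 it was 1208, and without experiment 1 or 4 it was 1450. Through wild type 290 genes were higher and 536 lower. That total of 826 was 201 with slide as a block, 1437 with set as a block and 2487 with a dye effect and experiment as random block, and leaving out any 1 of experiments 1 to 6 brought it to between 81 and 388. Fold changes of the direct comparison and through wild type correlated across genes with r of 0.814. Further large rises in the direct comparison were Apol10b (3.69 ± 0.82), Orm2 (3.54 ± 1.32), Cxcl1 (3.47 ± 1.27) and Tgtp1 (3.19 ± 0.37). Further large falls were Nfe2l2 (-6.49 ± 0.26, adjusted p = 7.61e-05), Cyp2a5 (-6.13 ± 0.31), Cyp2a4 (-5.66 ± 0.60) and Myot (-5.03 ± 1.60). Through wild type, on signals with the offset, Nfe2l2 gave -4.90. For 3 genes not well above background in one genotype only a bound is given, taken from the signals of experiments 2, 3, 5 and 6. Rbm45 was at least 1.46-fold higher, Styk1 at least 3.81-fold lower and Meig1 at least 1.67-fold lower. Sqstm1 was lower (-0.99 ± 0.11, adjusted p = 0.0088), and Atg7 (0.50 ± 0.75, adjusted p = 0.229) and Keap1 (-0.08 ± 0.07, adjusted p = 0.678) were not called. Further large differences through wild type were rises of Fgg (2.65) and Saa4 (2.44) and falls of Gsta2 (-4.81), Ces1g (-4.48) and Gstm1 (-4.39).

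In the direct comparison 22 of 24 genes of quinone, aldehyde and thiol reduction were lower and 0 higher (23 and 1 adjusted over the list alone; median -2.30, -2.26 and -2.17 in experiments 7 and 8; camera adjusted p = 1.5e-20). Of 21 glutathione genes 19 were lower and 0 higher (20 and 0 over the list alone; median -2.56, -2.23 and -2.47 in experiments 7 and 8; adjusted p = 1.07e-17). These 2 lists held with an estimated correlation (adjusted p = 0.0436 for both), the only list calls of any comparison that did. Through wild type their medians were -2.05 (-2.05 with slide as a block) and -2.13 (-2.12 with slide as a block). In the pentose phosphate pathway 5 of 9 genes were lower, such as Pgd at -1.98 (median -0.88, camera adjusted p = 3.67e-04, and 0.357 with an estimated correlation).

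Of 20 acute phase genes 15 were higher and 0 lower in the direct comparison (17 and 0 adjusted over the list alone; median 1.84, with 2.60 and 1.44 in experiments 7 and 8; camera adjusted p = 1.9e-11, and 0.454 with an estimated correlation). Through wild type the median was 1.65 (1.63 with slide as a block). Interferon genes had 15 higher and 1 lower of 28 (20 and 2 over the list alone; median 0.76, 0.76 and 0.86 in the 2 experiments; adjusted p = 3.34e-08, and 0.454 with an estimated correlation). Gbp2 lay at 2.40, against Mx1 at -1.25. Hepatocyte secreted proteins had 9 higher and 0 lower of 24 (median 0.33; adjusted p = 0.00104, and 0.17 with an estimated correlation), among them fibrinogen genes (Fgg at 2.49) and Ahsg at 1.32. The unfolded protein response had 5 higher of 22 (median 0.50; adjusted p = 3.67e-04, and 0.554 with an estimated correlation). Lymphocyte markers had 7 higher of 15 (0.92; adjusted p = 3.67e-04 and 0.192), such as Cd8a at 1.42. Neutrophil markers had 2 higher of 8 (1.27; adjusted p = 0.00775 and 0.454), with S100a9 at 2.27. Fatty acid oxidation had 8 lower of 32 (median -0.44, adjusted p = 3.91e-05 and 0.62) and the cell cycle 2 lower of 24 (-0.52, adjusted p = 0.00473 and 0.919). The cell cycle median was -0.08 in experiment 7 and -0.73 in experiment 8, so that call rests mainly on experiment 8. Macrophage markers were not called (2 higher, 1 lower of 17, median 0.28, adjusted p = 0.101), with Marco at 1.44 and Trem2 at -1.13. Cytochrome P450 (5 lower of 31, median -0.06), cholangiocytes (4 lower of 11, -0.22) and endothelium (1 lower of 15, -0.36) were not called. Neither were pericentral genes (3 higher and 1 lower of 11, 0.57), gluconeogenesis and glycolysis (2 higher and 4 lower of 20, -0.18), autophagy (1 higher and 3 lower of 29, -0.05), the urea cycle list (2 higher and 1 lower of 25, 0.01) or the remaining lists.

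**Figure D2:**
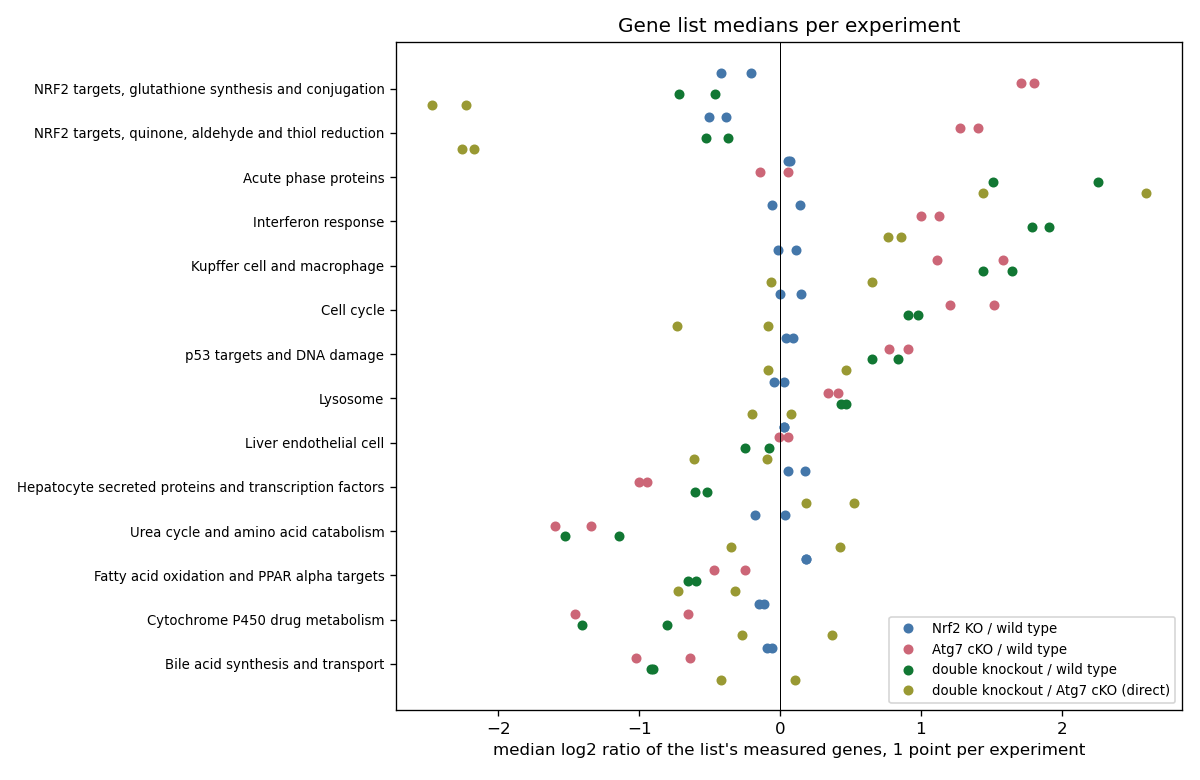
Median log2 ratio of the measured genes of 14 lists, 1 point per experiment, for Nrf2 KO, Atg7 cKO and the double knockout over wild type and for the double knockout over Atg7 cKO hybridised directly. The glutathione list lies at 1.80 and 1.71 in Atg7 cKO and at -0.46 and -0.71 in the double knockout, and acute phase proteins at 0.05 and -0.14 in Atg7 cKO and at 2.26 and 1.51 in the double knockout.

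A departure from additivity of the 2 knockouts was called for 120 genes (22 positive, 98 negative) by limma. With slide as a block the count was 0 (2639 at an unadjusted p under 0.05) and with set as a block 339, and leaving out any 1 of experiments 1 to 6 brought it to between 2 and 63. Adjusted over the list alone, 14 glutathione genes and 21 genes of quinone, aldehyde and thiol reduction departed downward and 0 upward, with medians of -1.70 and -1.23 (-1.62 and -1.17 with slide as a block). Adjusted likewise, 15 acute phase genes departed upward with a median of 1.49 (1.45 with slide as a block). Of the 3872 genes that rose in Atg7 cKO, 790 were lower in the direct comparison (20.4%, against 8.07% of all tested genes) and 248 were higher. Of the 2701 that fell, 324 were higher (12%, against 6.72% of all) and 75 lower. The 2 shares rest on separate hybridisations, and whether the RNA extracts were also separate is not in the labels. If they were the same, a gene high by chance in an Atg7 cKO liver would both count as risen and be lower in the direct comparison. That would raise the share of risers, and likewise that of fallers. Without experiment 7 the share of risers was 5.53% (against 1.45% of all genes), and without experiment 8 it was 9.87% (against 4.10%).

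Most fold changes of Atg7 cKO and the double knockout ran together. Across 16671 genes their log2 ratios correlated with r of 0.747 and a covariance of 0.222, against 0.501 and 0.00661 in 100 simulations with no effect and shared wild-type RNA. The simulations gave the shared wild type the same variance as the knockout, which sets the simulated r in advance. Measured r was 0.106 between Nrf2 KO and Atg7 cKO and 0.371 between Nrf2 KO and the double knockout. The simulated r is therefore no baseline for these data. Between experiments of different sets, which do not share a wild-type set, r was 0.615 (experiments 2 and 6) and 0.679 (experiments 5 and 3). A total of 2482 genes rose and 1674 fell in both, in comparisons that are not independent since both are with wild type, while 127 rose in Atg7 cKO and fell in the double knockout and 30 did the reverse. The shares of higher and lower genes depend on the scaling. With centring on the median 90.7% of called genes in Atg7 cKO and 85.7% in the double knockout were higher, against 58.9% and 57.2% with loess. The medians of all genes were 0.21 and 0.14 with centring. With the processed signals 48.6% and 46.4% were higher.

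**Figure D3:**
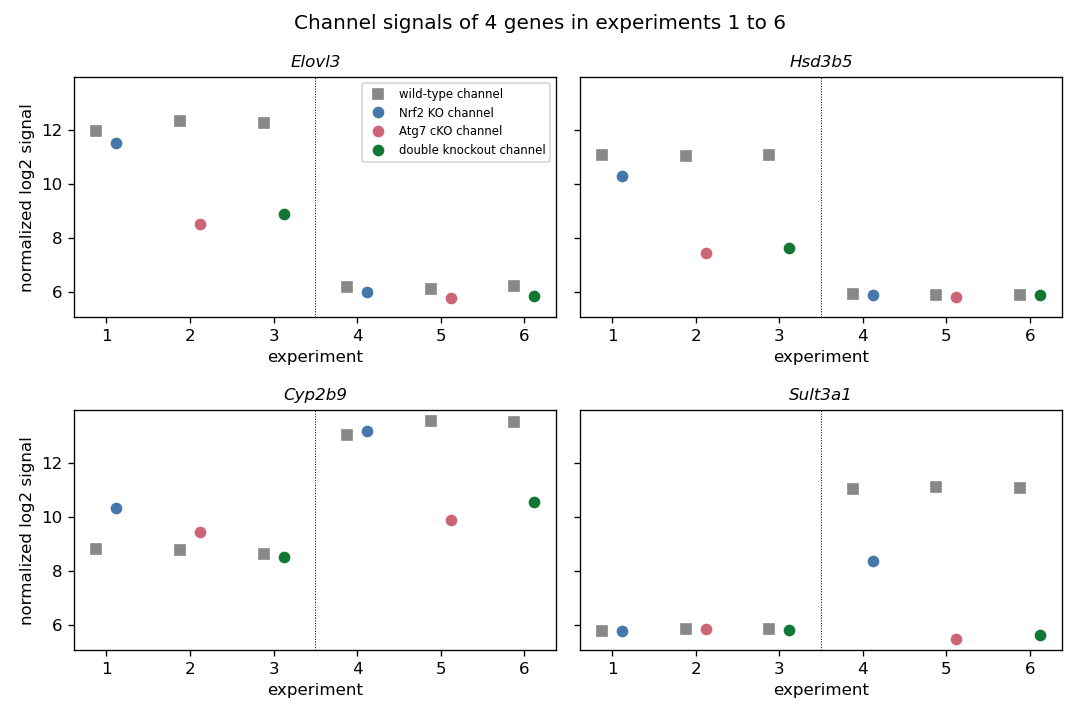
Normalised log2 signal of Elovl3, Hsd3b5, Cyp2b9 and Sult3a1 in the wild-type channel (squares) and the knockout channel (circles) of experiments 1 to 6, with a dotted line between experiments 3 and 4. Wild-type signals of the upper genes are high in experiments 1 to 3 and those of the lower genes in experiments 4 to 6, and in Atg7 cKO and the double knockout each lies below wild type in the set where wild type is high, with log2 ratios such as -3.79 and -3.37 for Elovl3 and -5.61 and -5.44 for Sult3a1.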

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

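The effect of losing Atg7 differed with and without Nrf2 by a test of the difference itself, the interaction on the log2 scale, for the genes and lists given here; the tests of explanations for the acute phase pattern were chosen after that pattern was seen. Negative values mean that the double knockout lay below the sum of both single knockouts. Among genes, Srxn1 lay at -4.11 and Maoa at -3.98 (limma adjusted p = 7.25e-04 for both), Gpx2 at -3.14 (adjusted p = 0.00154), Cbr3 at -3.25, Mgst3 at -3.18, Gsta1 at -4.69, Abcc4 at -3.37, Gstm4 at -2.20, Blvrb at -2.00 and Prdx1 at -1.01, of which all except Maoa belong to the lists of Nrf2 targets. Further negative values were -5.30 for Cyp2a5, -3.33 for Cyp2a22, -1.86 for Cyp1a2 and -1.75 for Krt23. Positive values were 2.10 for Mup1, 1.93 for Cebpb, 1.88 for Gvin1, 1.85 for Tgtp1, 1.76 for Itih3, 1.64 for Atp11a, 1.57 for Marco, 1.42 for Neurl3 and 1.29 for Gbp2, with adjusted p between 0.0163 and 0.0488. In the fit of the value table, the calls from Mup1 to Neurl3 were lost (limma adjusted p from 0.0744 to 0.196). Among the negative values, calls were lost for Abcc4 (limma adjusted p = 0.191), Prdx1 (0.16), Gpx2 (0.080), Cyp2a22 (0.066), Cbr3 (0.058) and Blvrb (0.051). Srxn1 (0.001125), Maoa (0.002139), Gsta1 (0.0279), Mgst3 (0.0309), Cyp2a5 (0.0455) and Gstm4 (0.0455) kept theirs. Mup1 signals were close in the double knockout and Atg7 cKO (log2 10.12 and 9.98), so its value reflects mostly the lower level in Nrf2 KO (-1.78). With experiments 1 to 3 against 4 to 6 as a block all 23 genes kept the call (339 genes in all). With slide as a block none passed (0 genes by limma, 2639 at an unadjusted p under 0.05), though folds of the 23 moved by at most 0.425 and their median standard error went from 0.193 to 0.178. Srxn1 went from -4.11 ± 0.10 to -4.07 ± 0.12 (standard error; adjusted p = 0.0527). The calls ended with 1 residual degree of freedom in place of 3, and the folds did not vanish.

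Lists with an interaction by camera at the preset correlation were glutathione targets of Nrf2 (median -1.70, adjusted p = 3.7e-18), targets in quinone, aldehyde and thiol reduction (-1.23, 1.83e-22), the pentose phosphate pathway (-0.52), fatty acid oxidation (-0.45), the cell cycle (-0.46) and endothelial markers (-0.25) on the negative side. On the positive side were acute phase proteins (1.49, adjusted p = 2.32e-15), the interferon response (0.62), the unfolded protein response (0.57), hepatocyte secreted proteins (0.36), neutrophil markers (0.25) and lymphocyte markers (0.19). None of the lists with an interaction passed with an estimated correlation, where adjusted p ran from 0.11 for the Nrf2 targets and hepatocyte proteins and 0.312 for acute phase proteins to 0.806 for endothelial markers.

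Acute phase genes were higher in the double knockout than in Atg7 cKO. A single experiment or a single set as the source was argued against, since the list's median difference was 2.04 in experiments 1 to 3, 1.33 in experiments 4 to 6, and 2.60 and 1.44 in direct experiments 7 and 8, with 1.33 the smallest. More macrophage RNA in the double knockout was argued against as the whole cause, since the acute phase median exceeded the macrophage median by 1.95 and 1.51 in experiments 7 and 8 (two-sided permutation of members between the lists, p = 1.9e-04). That permutation treats the members of a list as independent, so its p-value may be too small. Neutrophil markers (medians 1.74 and 0.92) and lymphocyte markers (1.13 and 0.59) were also higher in experiments 7 and 8, so a contribution of these cells stays open. Values of experiments 7 and 8 come from the value table, without the offset that shrinks dim genes. With the offset, neutrophil median differences were 0.25 in experiments 1 to 3 and 0.28 in experiments 4 to 6. Those of lymphocytes were 0.22 and 0.32. Experiments 7 and 8 may also carry the same RNA extracts as the others. An effect of the loss of Nrf2 on hepatocytes, chance differences between animals, an infection or a change of macrophages' own activity stay open, and the labels give nothing with which to test them.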

How the results depend on the processing

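The filter of 12 channels for the direct comparison and the 2-fold counts of single experiments were chosen after the data were seen; the other alternatives were planned. Of single results (genes, lists) under those planned, 19945 kept direction and side of the threshold, 1503 lost the call, 469 gained one and 12 reversed; of counts and shares 116 stayed within their limits and 65 moved. The correlation of Atg7 cKO with the double knockout stayed between 0.684 and 0.779. Where no reason is given, the cause was not tested. Counts run in the order given.

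Genes called through wild type and by interaction were 215 and 5 with processed signals, 214 and 6 with the value table, 380 and 66 with median centring (Nrf2 KO 0), 2487 and 1208 with a dye effect and experiment as random block (Nrf2 KO 91), 201 and 0 with slide as a block (Nrf2 KO 4) and 1437 and 339 with set as a block (Nrf2 KO 11). Nrf2 KO had 1 gene without background correction or without a filter. Scaling gave 4 for Nrf2 KO and 44 for the interaction, and Cy5 alone 5 and 184. With only a comparison's own experiments, where fewer residual degrees of freedom remain, Nrf2 KO had 1 gene, Atg7 cKO 3439, through wild type 81 and direct 107. A 2-fold minimum left 1041 in Atg7 cKO, 1064 in the double knockout, 281 through wild type and 1008 direct; adjusted p under 0.01 left 0, 3347, 3204, 82 and 512 for Nrf2 KO, Atg7 cKO, double knockout, through wild type and direct, and 13 interactions. The direct count was 5680 with all 8 experiments linked, 1966 with no filter and 2625 with 12 channels. The share of risers was 11.39% at adjusted p under 0.01 (2.255% of all genes). It was 11.18% through wild type (3.215% of all) and 32.52% with the experiments linked (16.59% of all), but these fits reuse experiments 2 and 5 with the opposite sign, which can raise the share by chance.

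Leaving out 1 experiment gave 0 to 2 genes in Nrf2 KO, 3205 (without 5) to 5954 in Atg7 cKO, 2857 (without 3) to 6236 in the double knockout, 81 (without 1 or 4) to 388 through wild type, 2 (without 1 or 4) to 63 interactions, 307 (without 7) to 1864 direct, and a share of 5.53% (without 7) to 23.37%. A lone experiment adds no residual degrees of freedom and is assumed to vary like the others.

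Reversed were Psmc1 in Atg7 cKO (0.21) and Sel1l in the double knockout (0.018) with median centring, which raised the median of all genes. In Nrf2 KO these were the proteasome with Cy5 alone (0.0052, camera's direction) and without experiment 1 (-0.039; 0.17 without 4), cholesterol synthesis without experiment 1 (0.16; -0.54 without 4), hepatocyte proteins with Cy3 alone (-0.13), and with slide as a block male-biased (0.11) and female-biased genes (-0.33). Slide as a block also reversed female-biased genes through wild type (0.59) and in the interaction (0.89), and cytochrome P450 in the interaction (0.63; 0.62 without experiment 2, -0.22 without 5). The fit with set as a block ties experiments 1 to 3 and 4 to 6; no pairing by animal was possible because the labels give no animal numbers. Low signal over background limits ratios of dim genes, which the offset shrinks.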

Other observations

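The tests on macrophage and hepatocyte markers were chosen after those results were seen; the tests on the sets of experiments were written before theirs. In the groups without Atg7 the hepatocyte list was called lower (1 higher and 19 lower of 24 in Atg7 cKO, 6 higher and 14 lower in the double knockout). The macrophage list was called higher, and neither call held with an estimated correlation. A smaller share of hepatocytes that raised all other cell types alike was argued against, since the macrophage median exceeded the endothelial median by at least 1.05 in each of the 4 experiments. In the means of both experiments the gap was 1.32 in Atg7 cKO and 1.64 in the double knockout (permutation p = 7.1e-04 and 1e-05, the latter the smallest that the permutations can give). The permutation treats the genes of a list as independent, and this pair of lists was picked after its medians were seen. These p-values may thus be too small. Background correction and normalisation were argued against only as the source of the gap between the 2 lists. The macrophage minus hepatocyte gap stayed at or above 1.61 over 10 processing alternatives, some of which changed only the filter, flags or probes. A shift of a whole array cancels in this gap, so the test cannot place either list against wild type. More macrophages, more expression per macrophage and lower expression per hepatocyte may each contribute and were not told apart here. Cre under the Mx1 promoter is known to act in blood cells too, so loss of Atg7 within macrophages stays open as well.

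Wild-type signals differed between experiments 1 to 3 and 4 to 6 in genes that are sex-biased in mouse liver. In the wild-type channels Elovl3 stood at 11.96 to 12.31 in experiments 1 to 3 and 6.13 to 6.21 in experiments 4 to 6 (log2 signal), while Sult3a1 stood high in experiments 4 to 6 alone. Log2 ratios of Elovl3 in Atg7 cKO were -3.79 in experiment 2 and -0.34 in experiment 5, and that of Sult3a1 was -5.61 in experiment 5, and -2.67 in Nrf2 KO experiment 4. Among genes against the pattern, Cyp4a12a rose by 2.90 in experiment 5, and Cyp2a4 rose in both Atg7 cKO experiments (5.22 and 2.88) and lay lower in both double knockout experiments (-1.75 and -2.76). The wild-type signal of Cyp2a4 was 9.71 in experiment 2, against 12.06 and 12.22 in experiments 1 and 3. It was 12.15 in experiment 5, against 13.7 and 14.4 in experiments 4 and 6. Part of the Cyp2a4 rise thus lies in low wild-type signals. For genes that differed at least 2-fold between the sets, chosen on wild-type channels of other arrays, the gap between sets in the knockout was a fraction of the wild-type gap, expressed as a slope. The slope was 0.748 in Nrf2 KO over 211 genes (95% interval over 1000 resampled gene sets 0.668 to 0.808). It was 0.189 in Atg7 cKO (0.139 to 0.242) and 0.308 in the double knockout (0.242 to 0.384), over 195 genes each. The intervals resample genes only, treat them as independent and hold no spread between animals.

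Selection of genes on noisy wild-type values was argued against, since the slope in Nrf2 KO stayed above the others by at least 0.440. Genes for Nrf2 KO were chosen on an average of wild-type gaps and those for the other groups on a single gap. The slopes are therefore not fully like for like. Compression of dim signals was argued against, since the gap was still at least 0.334 among genes well above background in all channels, where the slopes were 0.679, 0.211 and 0.345. Loss of sex-biased liver expression when Atg7 is absent may explain the smaller gap, if the sets are of different sex, which the labels do not say. Other differences between the sets stay open, since each set had 1 experiment per comparison.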
